A study of Homo sapiens with 6 samples.

How the data were processed

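The 6 libraries of U2OS 2-6-3 cells were grouped by the transfection given in the labels, 2 per group. RNA was isolated and directional libraries were made with commercial kits, per the labels' protocols. Bowtie, STAR, DESeq2 and the build hg38 are named in the submitters' processing notes; versions, roles, annotation and counting are not given in the sources used here. The deposited data are 3 tables of comparisons, each fitted by the authors on its own 4 libraries. Per the file headers they hold, for 40029 transcript entries, a mean signal of normalized read counts, the authors' log2 fold change and its standard error, a Wald score, and the authors' p-value and adjusted p-value. The deposited fold changes are shrunk toward 0, as the values show, so they understate changes of low or variable genes, most of all between sample and mock cells.

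Each deposited mean signal is a sum of whole counts divided by size factors over 4 libraries, so the counts of all 6 libraries could be solved from the 3 tables by lattice reduction. All 30527 entries with reads had whole counts that met the 3 tables within a relative tolerance of 1e-14. On simulated data 29693 of 29693 entries were recovered. Which library of a group is which replicate number is not known, so the deeper is called a and the shallower b. Totals ran from 9579278 to 54177551 reads summed over entries, in which isoforms of a gene can share reads. Accessions were matched to symbols for 39722 entries (99.2%), through a RefSeq gene table and then GENCODE 29, and the entry with the most reads stood for its gene. Entries without a symbol, 307 in number, held 0.067% of reads.

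A choice made before the data were examined was to use the authors' own DESeq2 results, at an adjusted p under 0.05, where no raw counts were given, and edgeR where they were. The tables hold no raw counts, so the deposited results are the main ones and edgeR was not run. Counts recovered from the means were tested with limma-voom (limma 3.58.1, R 4.3.3), an alternative chosen after seeing the data, on genes with a mean normalized count of at least 10, with median-of-ratios library sizes and Benjamini-Hochberg adjustment. On data simulated with a dispersion of 0.01 for mock against untransfected cells it recovered 100% of genes raised 2-fold and 96% of those set to 0.5. For sample against untransfected cells the shares were 98% and 94%, and for sample against mock cells 98% and 92%. All libraries were simulated with that same dispersion, whereas the real sample pair differed by an SD of 0.419 log2 units against 0.21 in the mock pair. The shares for comparisons with sample cells can therefore be too high. Gene lists, 25 in number and also fixed in advance, were tested with cameraPR on the deposited Wald score at a preset correlation of 0.01, adjusted over 72 tests. They were also tested with camera at an estimated correlation on the recovered counts. That fit had few residual degrees of freedom, and no list passed with it in any comparison. Not passing there does not by itself argue against a list. In mock against untransfected cells the estimated correlation was 0.67 for histones, 0.61 for ribosomal proteins, 0.57 for metallothioneins and 0.33 for immediate early genes. Preset at 0.01, cameraPR can give such lists p-values that are too small. The list of mitochondrially encoded genes had under 3 tested members and was not tested. Named genes were the 12 highest and 12 lowest called genes per comparison with a mean of at least 50, up to 4 called members per list, up to 2 abundant members of lists with none called, and a fixed set of genes given whatever their result. Some genes that meet these rules are not reported here. Genes near the array were compared with 10000 random lists matched on expression. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives changed the threshold, the filter on low counts, the null distribution, the centring, the test and the libraries kept.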

Results

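Transcript abundance was measured by RNA sequencing in U2OS 2-6-3 cells, a human osteosarcoma line with a chromosomal array of tet operators beside a reporter gene. The reporter RNA carries MS2 stem loops and codes for a cyan fluorescent protein with a peroxisomal signal. The 6 libraries fell into 3 groups of 2, all kept under white light overnight. The first group was left untransfected. The mock group received plasmids for red fluorescent TetR and for YFP. The sample group received CIBN-TetR, PHR-YFP-VP16 and mCherry-MCP, in which blue light joins PHR to CIBN and so brings the VP16 activator to the tet operators. Reads summed over transcripts were 53596406 and 51146190 in the untransfected libraries, 54177551 and 44594507 in the mock libraries, and 50105854 and 9579278 in the sample libraries, the last being the shallowest. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

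Among called sequences the reporter differed most between the transfected groups, and it addressed whether its RNA was higher with the light-controlled plasmids. All groups were kept under white light, so dependence on light was not tested. The plasmids differed in more than the activator, mCherry-MCP among them, so a rise cannot be assigned to the activator alone. The cyan fluorescent protein sequence stood at 27.5 ± 1.57 normalized read counts in untransfected cells, 61.6 ± 3.16 in mock cells and 24274 ± 736 (SD, n = 2) in sample cells. The MS2 loop sequence stood at 71.1 ± 18.9, 131 ± 22.5 and 4498 ± 1394 (SD, n = 2) in the same order. Both rose in sample against mock cells, with log2 fold changes of 6.31 (SE 0.10) and 2.90 (SE 0.12) in the authors' deposited table, which shrinks fold changes toward 0. The limma estimates from the recovered counts, without that shrinkage, were 8.61 (ECFP-SKL, adjusted p = 7.77e-09) and 5.13 (MS2loops, adjusted p = 0.000132). Against untransfected cells the deposited log2 fold changes of ECFP-SKL and MS2loops were 9.47 and 5.07 for the sample group, and 1.04 and 0.84 for the mock group, in the authors' deposited table. The 2 reporter sequences did not rise alike. MS2 loop reads per 100 ECFP-SKL reads were 295.5 and 218.9 in untransfected, 230 and 193.8 in mock, and 22.1 and 14.8 in sample libraries. YFP differs from the cyan protein by few bases, so reads of the transfected YFP plasmids can be counted with ECFP-SKL. The mock group also carried YFP, but YFP RNA was not measured apart in either group. How much of the ECFP-SKL rise came from the array therefore cannot be told.

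**Figure D1:**
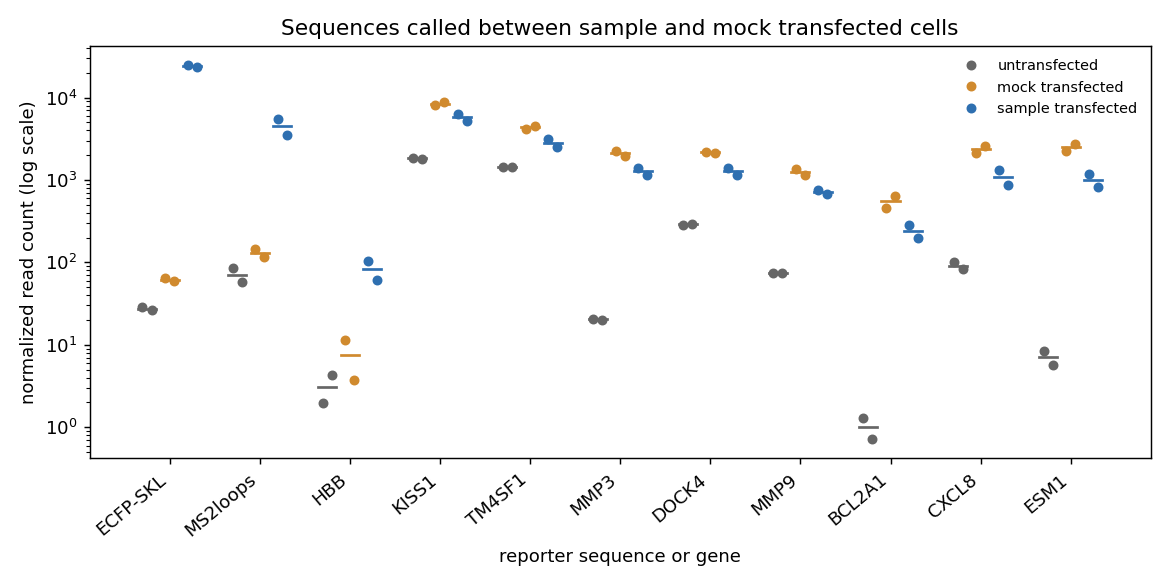
Normalized read count per library (points, log axis) and group mean (lines) for the 2 reporter sequences and genes called between sample and mock transfected cells. ECFP-SKL averaged 24274 in sample and 61.6 in mock cells, and both sample libraries lay below both mock libraries for each lower gene shown.

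Mock transfection, which addressed what transfection with the control plasmids does to these cells, raised ESM1, MMP3 and CXCL8 by large factors. ESM1, which codes for a secreted proteoglycan, stood at 7.07 ± 1.94 normalized read counts in untransfected and 2505 ± 335 (SD, n = 2) in mock cells. MMP3, a matrix metalloproteinase, stood at 20.4 ± 0.591 and 2111 ± 188 (SD, n = 2), and the neutrophil chemokine CXCL8 at 91.4 ± 12.3 and 2348 ± 311 (SD, n = 2). The authors' deposited table gave log2 fold changes of 7.84 (SE 0.26) for ESM1, 6.47 (SE 0.20) for MMP3 and 4.62 (SE 0.14) for CXCL8. KRTAP2-3, RDUR and MPP4 rose with log2 fold changes of 5.94 (SE 0.23), 4.95 (SE 0.30) and 4.77 (SE 0.30) in the authors' deposited table, though KRTAP2-3 has close paralogs that can share its reads. The transglutaminase TGM2 rose with 4.40 (SE 0.09), the TNF receptor adaptor TRAF1 with 4.39 (SE 0.19), the pentraxin PTX3 with 4.39 (SE 0.16) and the inflammasome sensor NLRP3 with 4.33 (SE 0.15) on the log2 scale of the authors' deposited table. BCL2A1, an anti-apoptotic gene, went from 1.01 ± 0.415 to 554 ± 128 (SD, n = 2) normalized read counts, and MYCT1 from 1.07 ± 1.51 to 135 ± 10.7 (SD, n = 2).

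WNT11 and CXCL14 were among the genes that fell most. WNT11, a Wnt ligand, stood at 589 ± 9.66 normalized read counts in untransfected and 5.05 ± 1.89 (SD, n = 2) in mock cells, and the chemokine CXCL14 at 2852 ± 73.5 and 80.7 ± 9.21 (SD, n = 2). Their log2 fold changes were -6.02 (SE 0.32) and -5.04 (SE 0.13) in the authors' deposited table. Log2 fold changes in the authors' deposited table were -5.51 (SE 0.29) for the pro-apoptotic gene BMF, -5.28 (SE 0.26) for the Wnt receptor regulator RNF43, -5.13 (SE 0.28) for LINC02159, -4.97 (SE 0.36) for the serotonin receptor HTR2A, -4.81 (SE 0.35) for TMPRSS3 and -4.78 (SE 0.32) for LINC00639. ATP10B fell from 189 ± 23.4 to 0.355 ± 0.501 normalized read counts, PRND from 173 ± 31.5 to 0.355 ± 0.501, FOXS1 from 160.1 ± 10.5 to 1.42 ± 2.01 and SECTM1 from 91.3 ± 6.93 to 0.355 ± 0.501 (SD, n = 2). At an adjusted p under 0.05, 8697 of 17101 genes were called, 4705 higher and 3992 lower, by the DESeq2 test of the authors' deposited table. Of these, 2686 had a log2 fold change of at least 1 either way in the authors' deposited table, 981 higher and 1705 lower.

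Among the fixed gene lists, NF-kB and inflammatory genes rose together in mock cells, with 16 higher and 1 lower of 21 tested, or 16 and 1 adjusted over the list alone (cameraPR adjusted p = 8.15e-15; adjusted p = 0.69 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB signalling, stood at 107 ± 9.85 normalized read counts in untransfected and 1024 ± 23.3 (SD, n = 2) in mock cells. Immediate early genes also rose, with 17 higher and 4 lower of 26 tested, or 17 and 5 adjusted over the list alone (cameraPR adjusted p = 2.11e-05; adjusted p = 0.69 with an estimated correlation). Within that list the log2 fold changes were 2.54 for MYC, 2.78 for the phosphatase DUSP5, 1.86 for CCN2 and 1.44 for CCN1 in the authors' deposited table. FOS, a founding member of the class, fell with a log2 fold change of -1.16 (SE 0.12) in the authors' deposited table. The metallothionein list rose, with 3 higher and 0 lower of 5 tested, or 3 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0032; adjusted p = 0.69 with an estimated correlation). Its called members were the metallothioneins MT2A, from 1982 ± 85.3 to 12179 ± 1198 (SD, n = 2) normalized read counts, and MT1E, and the zinc exporter SLC30A1, which is no metallothionein. The metallothionein list did not pass by ranks (adjusted p = 0.168), by percentile among random lists (95) or with limma's statistic (adjusted p = 0.114). The extracellular matrix list passed as higher although its members went both ways, with 13 higher and 11 lower of 27 tested, or 14 and 11 adjusted over the list alone (cameraPR adjusted p = 0.0168; adjusted p = 0.74 with an estimated correlation). COL6A3 rose (1.95 on the log2 scale) and the collagen gene COL5A2 fell (-2.11) in the authors' deposited table. This list did not pass under any of the alternatives tried, among them ranks of the statistic (adjusted p = 0.745).

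Sterol genes fell in mock cells, with 3 higher and 18 lower of 25 tested, or 3 and 18 adjusted over the list alone (cameraPR adjusted p = 0.00121; adjusted p = 0.69 with an estimated correlation). INSIG1, a sterol-responsive regulator, stood at 1653 ± 74.6 normalized read counts in untransfected and 400.1 ± 43.9 (SD, n = 2) in mock cells. Log2 fold changes were -1.09 for STARD4, -0.83 for LSS and -0.63 for FDFT1, whereas HMGCS1 rose by 0.39, in the authors' deposited table. Interferon-stimulated genes fell, with 2 higher and 17 lower of 36 tested, or 2 and 18 adjusted over the list alone (cameraPR adjusted p = 0.00327; adjusted p = 0.69 with an estimated correlation). IFIT1 went from 319 ± 14.1 to 36 ± 6.28 (SD, n = 2) normalized read counts, and SAMD9 from 883 ± 10.6 to 173 ± 34.5 (SD, n = 2). ISG15 fell with a log2 fold change of -0.51 (SE 0.17) in the authors' deposited table. The histone list fell, with 0 higher and 12 lower of 16 tested, or 0 and 12 adjusted over the list alone (cameraPR adjusted p = 0.0113; adjusted p = 0.69 with an estimated correlation). H3C4, H2BC5 and H4C3 had log2 fold changes of -0.95, -0.64 and -0.61 in the authors' deposited table. At a correlation of 0.05 neither interferon-stimulated genes (adjusted p = 0.075) nor histones (adjusted p = 0.0685) passed, and with limma's statistic histones did not (adjusted p = 0.0794). Histone genes are near-identical copies whose reads can be split between members.

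The other lists did not pass with cameraPR on the Wald score in mock cells, although many members changed singly. Of all 17101 tested genes 50.9% were called, 4705 higher and 3992 lower. Member counts near that share show no change particular to a list. By ranks of that score ribosomal protein genes (adjusted p = 0.00086) and heat shock genes (adjusted p = 0.0338) passed as higher. Neither list passed with limma's statistic (adjusted p = 0.252 and 0.114), nor with an estimated correlation (adjusted p = 0.84 and 0.69), with which no list passed. Their percentiles among random lists were 39.7 and 99. Heat shock genes had 11 higher and 3 lower of 17 tested, or 11 and 3 adjusted over the list alone, with log2 fold changes of 0.99 for HSPA8, 0.91 for HSPD1, -1.74 for CRYAB and -0.95 for HSPB1 in the authors' deposited table. Hypoxia and glycolysis genes had 16 higher and 8 lower of 29 tested, or 16 and 8 adjusted over the list alone, among them the hexokinase HK2, from 391 ± 20.3 to 2967 ± 42.6 (SD, n = 2) normalized read counts. Members called higher and lower numbered 11 and 12 of 26 for p53 targets (11 and 12 adjusted over the list alone), while CDKN1A had a log2 fold change of 0.01 (adjusted p = 0.887) in the authors' deposited table. Circadian genes had 6 higher and 6 lower of 22 tested, or 6 and 6 adjusted over the list alone, with log2 fold changes of -3.85 for DBP, -2.08 for TEF, 0.24 for CRY1 and -0.48 for CRY2 in the authors' deposited table. Counts adjusted over the list alone, higher and lower, were 1 and 0 of 10 for blood cell markers, 3 and 3 of 14 for cytosolic nucleic-acid sensors and 25 and 1 of 52 for cytosolic ribosomal proteins. They were 9 and 11 of 33 for DNA replication and S phase, 2 and 7 of 16 for epithelial cell markers and 4 and 11 of 32 for G2 and mitosis. Further counts were 11 and 10 of 25 for lysosome and autophagy, 5 and 6 of 18 for MHC class I and antigen presentation and 12 and 7 of 24 for NRF2 and oxidative stress genes. The remaining lists had 4 and 5 of 14 for osteoblast lineage genes, 7 and 3 of 16 for reference genes and 13 and 8 of 28 for unfolded protein and integrated stress response. There were 14 and 2 of 25 for VP16 partner and co-activator genes. Of genes set in advance to be given, DDIT3 rose (0.69), as did HCFC1 (0.32) and ACTB (0.56), and POU2F1 fell (-0.21), on the log2 scale of the authors' deposited table. Not called were HSPA1A (-0.05, adjusted p = 0.672), GAPDH (0.15, adjusted p = 0.0817) and HBB (0.59, adjusted p = 0.379) in the authors' deposited table.

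**Figure D2:**
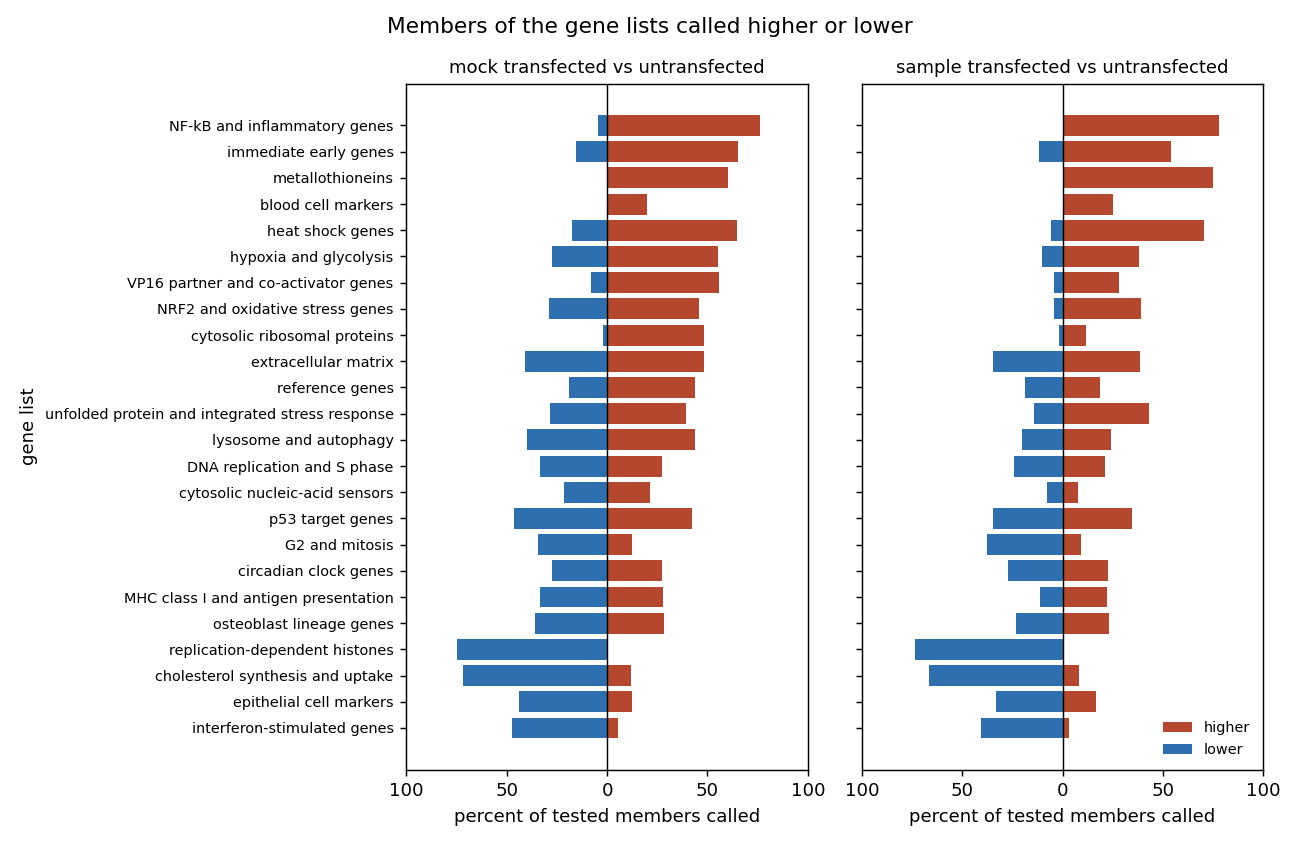
Percent of tested members called higher (right) or lower (left) per gene list in mock (left panel) and sample transfected cells (right panel) against untransfected cells, in the authors' deposited table. NF-kB and inflammatory genes had 16 of 21 members higher in mock cells, and histones had 12 of 16 lower. Of all tested genes 50.9% were called in mock and 37.3% in sample cells.

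Sample transfection against untransfected cells, which addressed what transfection with the light-controlled plasmids does, moved many of the genes named for the mock group. ESM1 averaged 997 ± 257 (SD, n = 2) normalized read counts in sample cells, MMP3 1284 ± 174 (SD, n = 2) and TGM2 7160.5 ± 1345 (SD, n = 2). The authors' deposited table gave log2 fold changes of 6.30 (SE 0.31) for ESM1, 5.62 (SE 0.23) for MMP3, 4.49 (SE 0.45) for KRTAP2-3, 4.26 (SE 0.15) for TGM2 and 4.25 (SE 0.23) for TRAF1. RDUR (4.24), MPP4 (3.83), PTX3 (3.83) and the ubiquitin ligase gene MARCHF4 (3.83) rose too, on the log2 scale of the authors' deposited table. BCL2A1 averaged 240.4 ± 60.5 (SD, n = 2) normalized read counts in sample cells. The dopamine receptor gene DRD1 fell from 2451 ± 209 normalized read counts in untransfected to 19.2 ± 3.84 (SD, n = 2) in sample cells, and the transcription factor gene SOX2 from 446 ± 73.4 to 13.6 ± 1.78 (SD, n = 2). Log2 fold changes were -6.35 (SE 0.25) for DRD1, -5.76 (SE 0.37) for WNT11, -4.76 (SE 0.20) for CXCL14, -4.51 (SE 0.21) for the sugar transporter SLC2A12 and -3.95 (SE 0.23) for the chemokine receptor ACKR3 in the authors' deposited table. LINC00639 (-4.42), LINC02159 (-4.31), HTR2A (-4.29) and SOX2 (-4.27) fell as well in the authors' deposited table. PRND had no reads in either sample library, ATP10B averaged 1.17 ± 1.66 and FOXS1 0.782 ± 1.11 (SD, n = 2) normalized read counts. At an adjusted p under 0.05, 5805 of 15576 genes were called, 3149 higher and 2656 lower, by the DESeq2 test of the authors' deposited table.

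In sample cells NF-kB and inflammatory genes rose, with 14 higher and 0 lower of 18 tested, or 15 and 0 adjusted over the list alone (cameraPR adjusted p = 2.49e-16; adjusted p = 0.69 with an estimated correlation). CXCL8 and the NF-kB subunit gene RELB had log2 fold changes of 3.39 and 2.26 in the authors' deposited table. Immediate early genes rose, with 14 higher and 3 lower of 26 tested, or 15 and 3 adjusted over the list alone (cameraPR adjusted p = 5.37e-05; adjusted p = 0.69 with an estimated correlation). MYC (2.58), DUSP5 (2.44) and CCN2 (1.99) were higher and FOS (-1.35) lower, as log2 fold changes of the authors' deposited table. Heat shock genes rose, with 12 higher and 1 lower of 17 tested, or 13 and 1 adjusted over the list alone (cameraPR adjusted p = 0.000356; adjusted p = 0.69 with an estimated correlation). HSPA8 (0.91), HSPD1 (0.81) and FKBP4 (0.65) were among its called members on the log2 scale of the authors' deposited table, while HSPA1A stood at 0.29 (adjusted p = 0.0528) and has a near-identical paralog. The co-chaperone gene BAG3 rose from 389 ± 10.6 to 1183 ± 424 (SD, n = 2) normalized read counts. The metallothionein list rose, with 3 higher and 0 lower of 4 tested, or 3 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0048; adjusted p = 0.69 with an estimated correlation). It did not pass by ranks (adjusted p = 0.127), by percentile among random lists (94.4) or with limma's statistic (adjusted p = 0.0628). Sterol genes fell, with 2 higher and 16 lower of 24 tested, or 2 and 17 adjusted over the list alone (cameraPR adjusted p = 0.000267; adjusted p = 0.69 with an estimated correlation). INSIG1 had a log2 fold change of -2.04 and HMGCS1 of 0.14 (adjusted p = 0.559) in the authors' deposited table. Interferon-stimulated genes fell, with 1 higher and 13 lower of 32 tested, or 1 and 13 adjusted over the list alone (cameraPR adjusted p = 0.00166; adjusted p = 0.69 with an estimated correlation). IFIT1 had a log2 fold change of -3.04 and ISG15 of -0.54 (adjusted p = 0.0839) in the authors' deposited table. The histone list fell, with 0 higher and 11 lower of 15 tested, or 0 and 11 adjusted over the list alone (cameraPR adjusted p = 0.000553; adjusted p = 0.69 with an estimated correlation). G2 and mitosis genes passed as lower by ranks (adjusted p = 0.0454), and epithelial markers as lower among genes with a mean of at least 50 (adjusted p = 0.0332). Neither passed with an estimated correlation (adjusted p = 0.69 each). A limma fit without the deeper sample library rests on the shallower one alone for that group. There the median log2 fold changes were 0.32 for extracellular matrix, 0.27 for oxidative stress, 0.22 for VP16 partner and -0.22 for G2 and mitosis genes. With all 6 libraries they were 0.02, 0.24, 0.20 and -0.15 in the same order. The first 3 of these lists did not pass with an estimated correlation (adjusted p = 0.76, 0.69 and 0.69). Of the genes given whatever their result, HBB (3.14) and ACTB (0.75) rose and CRY2 (-0.44) fell, on the log2 scale of the authors' deposited table. Not called were HCFC1 (0.75), POU2F1 (-0.19), CRY1 (0.17), DDIT3 (0.44), CDKN1A (0.20) and GAPDH (0.15) in the authors' deposited table.

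Both transfections moved genes in the same direction. Of 15564 genes tested in both comparisons, 3090 were higher in both, 2612 lower in both and 0 opposite, in the authors' deposited table, while 2895 were called in mock cells alone and 103 in sample cells alone. Independent lists would share 943 higher and 672 lower genes. With limma on the recovered counts 3621 genes were higher and 3559 lower in both. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.496 against 0.0113 in 20 simulations of unchanged groups set against the same untransfected libraries, and their correlation 0.973 against 0.479. With mock and sample cells set against different untransfected libraries the covariance was 0.494 and 0.489. Each of these used 1 untransfected library. Shared controls gave 0.496 by the same measure. These values argue against shared controls as the source of more than a small part of the covariance.

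Sample against mock cells was a comparison of the light-controlled plasmids with the control plasmids, which differ in several expressed proteins besides the activator. It left 12 of 15296 tested sequences called, 3 higher and 9 lower, by the DESeq2 test of the authors' deposited table. An unadjusted p under 0.05 was seen for 299, fewer than the share of 0.05 that unchanged sequences alone should give. The Wald scores were also narrowly spread, with an SD of 0.767 estimated from their median absolute deviation. The deposited test was therefore cautious here, and the few calls do not show that the groups were nearly equal. The cause of this caution was not tested. Besides the 2 reporter sequences, HBB, the adult beta-globin gene (chromosome 11, 5225466 to 5227071, hg38), was higher. It averaged 7.53 ± 5.4 normalized read counts in mock and 82.5 ± 29.3 (SD, n = 2) in sample cells. It had a log2 fold change of 0.38 (SE 0.09) and an adjusted p of 0.0191 in the authors' deposited table. HBB reads numbered 132 and 15 in the sample libraries and 16 and 4 in the mock libraries. HBD, its paralog, with which reads can be shared and which was looked up after HBB was seen, had 55 and 10 reads in the sample and 5 and 8 in the mock libraries. In normalized read counts HBD stood at 43.0 and 41.2 in the sample and 3.55 and 7.42 in the mock libraries, and was not called. The 9 lower genes were all raised by mock transfection. ESM1 averaged 2505 ± 335 normalized read counts in mock and 997 ± 257 (SD, n = 2) in sample cells, CXCL8 2348 ± 311 and 1086 ± 308 (SD, n = 2), and MMP9, another metalloproteinase, 1264 ± 146 and 719 ± 50 (SD, n = 2). DOCK4 averaged 2159 ± 11.6 and 1278 ± 189 (SD, n = 2), TM4SF1 4353 ± 268 and 2829.7 ± 485 (SD, n = 2), and KISS1 8461 ± 574 and 5733 ± 794 (SD, n = 2). Deposited log2 fold changes were -0.85 (SE 0.12) for ESM1, -0.69 (SE 0.12) for CXCL8, -0.56 (SE 0.12) for BCL2A1, -0.55 (SE 0.12) for MMP9 and -0.54 (SE 0.11) for DOCK4 in the authors' deposited table. MMP3 (-0.51), TM4SF1 (-0.46) and KISS1 (-0.43) were also lower on the log2 scale of the authors' deposited table. With limma on the recovered counts only ECFP-SKL and MS2loops passed with all 6 libraries. There, without shrinkage, HBB had a log2 fold change of 3.68 (adjusted p = 0.142) and ESM1 of -1.22 (adjusted p = 0.0887). Without the deeper sample library 841 sequences passed in limma, all 12 called ones among them. Without the shallower one 7 passed, namely both reporter sequences, HBB, ESM1, CXCL8, DOCK4 and MMP9. The shallower library differed from the deeper one by an SD of 0.419 log2 units against 0.21 in the mock pair.

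Against mock cells NF-kB and inflammatory genes were lower in sample cells, with 0 higher and 1 lower of 19 tested, or 0 and 3 adjusted over the list alone (cameraPR adjusted p = 3.46e-06, adjusted p = 0.69 with an estimated correlation). As a list these genes had risen in both transfected groups against untransfected cells. Whether a smaller response to transfection in sample cells, not particular to this list, gave the shift was not tested. Ribosomal protein genes were lower as a list, with 0 higher and 0 lower of 52 tested, or 0 and 0 adjusted over the list alone (cameraPR adjusted p = 4.78e-06; adjusted p = 0.69 with an estimated correlation). Heat shock genes were higher as a list, with 0 higher and 0 lower of 17 tested, or 4 and 0 adjusted over the list alone (cameraPR adjusted p = 3.85e-06; adjusted p = 0.69 with an estimated correlation). In limma their median log2 fold change was 0.24 with 6 called higher without the deeper sample library, and 0.04 with 0 called without the shallower one, so the size of the shift lay mostly in the shallower library. RPL8 and RPL4 had log2 fold changes of -0.09 and -0.08, HSPA8 and HSP90AB1 of -0.05 and 0.08, and HSPA1A of 0.28, none of them called in the authors' deposited table. With limma's statistic the ribosomal list did not pass without the deeper sample library (adjusted p = 0.0989). Immediate early genes passed as higher without that library (adjusted p = 0.0133) but as lower without the shallower one (adjusted p = 0.00578). At an unadjusted p under 0.05 the DESeq2 test had 0 ribosomal, 5 heat shock and 1 VP16 partner genes. Ribosomal protein genes have many pseudogenes that can share their reads. Their median log2 fold change was only -0.08 in the authors' deposited table. Their estimated correlation was 0.62, far above the preset 0.01, so the cameraPR p-value can be too small. At a preset correlation of 0.05 the cameraPR adjusted p was 0.00887. The VP16 partner list had 0 higher and 0 lower of 25 tested, or 0 and 0 adjusted over the list alone. In limma without the deeper sample library it passed as higher, with 7 higher and 0 lower (adjusted p = 0.00142), and so did osteoblast lineage genes (adjusted p = 0.0153), whose median log2 fold change was slightly negative. With limma's statistic on all 6 libraries extracellular matrix genes passed as lower (adjusted p = 0.0225) and p53 targets as higher (adjusted p = 0.0286). Blood cell markers also passed as higher (adjusted p = 0.0225), with a negative median log2 fold change of -0.04. That list had 5 tested members, 0 of them called, and holds HBB, at 3.68 in limma. Its result without HBB was not tested. With an estimated correlation none of these 3 lists passed (adjusted p = 0.69 each). Without the shallower sample library histones (adjusted p = 1.96e-10) and extracellular matrix genes (adjusted p = 0.00641) passed as lower and p53 targets as higher (adjusted p = 0.000113), and without the deeper one extracellular matrix genes, p53 targets and blood cell markers did not pass. HCFC1, a VP16-binding host factor, had a log2 fold change of 0.12 (SE 0.10) and POU2F1, another, of 0.03 (SE 0.11) in the authors' deposited table. HCFC1 averaged 2192 ± 83.7 normalized read counts in mock and 3419 ± 1756 (SD, n = 2) in sample cells, where the deeper library stood at 2177 and only the shallower one, at 4661, lay above both mock libraries. CRY1 and CRY2, relatives of the plant photoreceptor behind PHR, stood at -0.04 and 0.03, and GAPDH and ACTB at 0.03 and 0.16, on the log2 scale of the authors' deposited table. IFIT1 (-0.06), ISG15 (-0.02), DDIT3 (-0.09), CDKN1A (0.17), FOS (-0.11) and HMGCS1 (-0.17) were not called either in the authors' deposited table.

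Genes near the reporter array, which is known to sit in the distal short arm of chromosome 1, could hardly be judged by calls between sample and mock cells. Of 288 tested genes in the first 28 Mb of chromosome 1 (hg38), 0 were called by DESeq2, but so were only 0.067% of the other tested genes. An unadjusted p under 0.05 was seen for 7 of the 288, beside 299 of all 15296 tested sequences. The median log2 fold change of the 288 genes was 0.01 in the authors' deposited table. That median lay at percentile 97.9 among 10000 random lists matched on mean expression, at 77.6 for the first 14 Mb and at 99.7 for genes with a mean of at least 50. Against untransfected cells the medians near the array were 0.08 in mock and 0.11 in sample cells, at percentiles 97.2 and 99.9, in the authors' deposited table.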

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

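The tests of the shallower library alone and of HBB were chosen after the result was seen, and the reading of the slope test against the median of the 9 genes was settled after its value was seen, a first reading against their highest value having favoured the explanation. By the deposited DESeq2 test of the difference itself, the effect of sample transfection differed from that of mock transfection in 10 genes. With limma on all 6 libraries none of these 10 genes passed, the lowest adjusted p being 0.0887 for ESM1. Among them the log2 fold changes, sample over mock, were -0.85 for ESM1, -0.69 for CXCL8, -0.56 for BCL2A1, -0.55 for MMP9, -0.54 for DOCK4, -0.51 for MMP3, -0.46 for TM4SF1, -0.43 for KISS1 and 0.38 for HBB in the authors' deposited table.

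The 9 lower genes do not rest on the shallower sample library alone, since the deeper one lay below both mock libraries for 9 of 9. A smaller response to transfection overall remains open as a part of the pattern. Over 136 genes raised at least 4-fold in the deeper mock library, the response of the deeper sample library was 0.899 of that of the other mock library (95% bootstrap interval 0.888 to 0.912). The interval came from resampling genes, which are not independent, with no replicate library on either side, so it leaves out the spread between libraries. Genes chosen for their rise in a mock library can also lean toward a larger mock response. Over 277 genes lowered at least 4-fold in the deeper mock library the ratio was 0.898. For the 9 genes the ratio ran from 0.687 to 0.925 with a median of 0.803, so the ratio over the 136 genes fell between their median and their highest value. Of the 9 genes, 8 had a ratio under the bootstrap interval. Genes picked for being low also lean low. The different plasmids of the groups are a biological explanation that was not tested.

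HBB may be counted from reads of globin sequence in the reporter array, which is known to carry part of a rabbit beta-globin gene. HBB reads per 100 MS2 loop reads were 1.88 and 1.76 in the sample libraries (two-sided Fisher's exact test p = 0.894, covering counting error only, since reads are not independent molecules), and 0.416 and 0.26 per 100 ECFP-SKL reads. With 15 HBB reads in the shallower library the test has little power, and activation of HBB itself would also allow the ratio, so the explanations cannot be told apart. Activation of every gene of the beta-globin cluster is argued against by HBE1, its most abundant gene here, whose sample over mock log2 ratio was -0.079. HBD, of the same cluster, went the other way, at 43.0 and 41.2 normalized read counts in the sample and 3.55 and 7.42 in the mock libraries, so activation of HBB and HBD together stays open, as do reads shared between them.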

How the results depend on the processing

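The limma tests, the estimated correlation, the counting of every transcript entry and the limma fits with a library left out were chosen after seeing the data. No paired analysis was possible because the recovered libraries carry no replicate numbers, and the planned DESeq2 and replicate block alternatives were not run. With a library left out, the lone library of its group is assumed to vary like the others. Counts against untransfected cells stayed within 1.5 times of 8697 (mock) and 5805 (sample) under other thresholds, filters, centring, tests and left-out libraries, with 2 exceptions: they ran from 6635 to 12899 and 4391 to 8691, and with a library left out from 6635 to 10087 and 5427 to 8257. A minimum log2 fold change of 1 gave 2686 and 1856, and an empirical null, which rescales the statistic to the spread of the middle genes, 1267 and 747. Between sample and mock cells the count of 12 became 6 at 0.01, 2 with that minimum fold change, 48 with the empirical null, 2 with limma on all 6 libraries and 2 on the 4 compared. With limma and 1 library left out it ran from 2 to 841: 2 without any untransfected or mock library, 7 without the shallower and 841 without the deeper sample library. The causes of these changes were not tested. Lists passing numbered 7, 7 and 3 for mock and sample against untransfected and sample against mock cells, and 0 in each with an estimated correlation, a fit with few residual degrees of freedom. For mock cells they were 4 at a correlation of 0.05 and 4 with limma's statistic. Between sample and mock cells they were 6 by percentile among random lists, 6 with limma's statistic and 5 without the deeper or 7 without the shallower sample library. For sample against untransfected cells the numbers were 11 and 7. The percentile of genes near the array moved from 97.9 to 77.6 for the first 14 Mb in sample against mock cells but to 99.7 at a mean of at least 50, and in mock against untransfected cells from 97.2 to 97.6 for 14 Mb and 98.1 at a mean of at least 50. The 14 Mb value for sample against mock cells fell short of the two-sided bound of 0.05 that its main value passed, and both mock alternatives passed the bound that their main value missed. Of 247 named and called values, 233 passed in limma in the same direction, and none reversed. Between sample and mock cells only 2 of these values passed, both of reporter sequences, and 10 did not. The depth of the shallower sample library limits low genes.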

Other observations

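The tests of GC content and of the thinned library pair were set before their results were seen, and those of the call numbers and of the GC trend as the whole cause after. The shallower sample library stood apart from the deeper one. Over 12578 genes with a mean normalized count of at least 50, the SD of their log2 difference was 0.419, against 0.21 in the mock and 0.175 in the untransfected pair. Among 5519 genes with a mean of at least 1000 the SDs were 0.252, 0.125 and 0.099.

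Lower depth alone is argued against, since the mock pair with its shallower library thinned to the same depth reached an SD of at most 0.296 over 10 thinnings. A GC trend was present and may be a part of the difference: GC content and the log2 difference had a Spearman rho of 0.303 across genes, just past the bound of 0.3 set for it, against 0.162 and 0.135 in the other pairs. It is not the whole, because removing the median of each GC decile left an SD of 0.403. Depth was also not the whole of the smaller number of calls in sample than in mock cells, though it may be a part. With limma, mock against untransfected cells gave 10118 calls unthinned and 9584 to 9689 when thinned, against 7155 for sample cells. No biological explanation was tested, since both libraries belong to 1 group.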
